A study of Mus musculus with 6 samples.

How the data were processed

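Total RNA from the testes of 6 male mice, 3 wild type (WT) and 3 lacking Prss54 (Prss54KO), all 6 to 8 weeks old and of a mixed 129Sv and C57BL/6 background, was measured on 1-colour Agilent mouse expression arrays, 1 array per mouse. Per the labels' protocols, 0.5 ug of RNA per sample was labelled with Cy3. The labels give no litter, and limma's p-values for single genes measure the spread between these 3 animals per genotype. Permutations over genes, Fisher's exact tests and camera at a preset correlation take genes as the units. Their p-values do not measure the spread between animals.

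The deposited scanner files hold the intensity of each spot on a linear scale. Per the file headers they were written by Agilent Feature Extraction version 10.7.3.1, and per the submitters' processing notes by Feature Extraction version 10.7. The processed signal in these files is the spot's brightness after the scanner software's own background treatment. Other columns of the deposited files hold marks for spots that are well above background, saturated or outliers. Probe positions are those of the mm9 mouse build, per the file headers. The deposited table of the whole series holds log2 values. Its 6 columns have identical quantiles, with a median of 7.72 in each and a range of 2.71 to 18.95, so it is quantile normalized between arrays. Each column correlated with the log2 processed signal of its own array at r of 0.999 or more over probes. The table was used as an alternative input only. The software that made it is not given in the sources used here.

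Each array had 45018 spots, of which 43379 detect genes, on 41174 different probes with 27376 gene names. Between 66.2% and 74.8% of the gene spots were well above background on an array, and 0 were saturated. Between 86 and 142 outlier-marked gene spots per array were left out. The gene names are those of the array's design and can be old. Of the probes, 27668 matched the RefSeq table (assembly GRCm38.p6) by accession and 6057 by symbol or synonym, and 7449 matched no entry. That table was used for names and for the order of neighbouring genes only, because its build differs from that of the files. No genome sequence or mm9 annotation was used here, so the exon or untranslated region under a probe is not given.

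Unless stated otherwise, choices in this paragraph were made before the data were examined. The log2 of the processed signal minus the array's 75th percentile was the measured level. Spots of 1 probe were averaged, probes well above background on at least 3 of the 6 arrays were kept (28923 probes), and each gene name was represented by its brightest probe over all 6 arrays, which left 19398 genes. Genotypes were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are Prss54KO minus WT on the log2 scale, and SE is limma's moderated standard error. The 26 gene lists had been fixed for germ cell stages, sperm structures, somatic testis cells, cells that dissection can carry along, and stress or metabolic pathways. Of their 871 entries, 804 matched a gene name of the files directly, 38 matched through RefSeq and 29 did not match. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, and again with camera at an estimated correlation and with fry, adjusted over the lists. Genes near Prss54 were compared with all other genes by a two-sided permutation test of the mean absolute log2 difference (100000 permutations). The fixed distances were 10 Mb and 1 Mb, with Fisher's exact test for counts of genes past the threshold. No gene passed, so the Fisher's tests reported use counts at an unadjusted p under 0.05, a choice made after the data were seen.

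The text names genes by a fixed rule: Prss54 with its probe; up to 12 genes per direction with the largest difference among those past the threshold, filled to 5 per direction by the smallest unadjusted p where fewer passed, with a gene symbol and well above background on all 3 arrays of the higher genotype; from each list up to 4 members past the threshold or else the 2 with the smallest unadjusted p; and genes within 1 Mb of Prss54. Members of the fibroblast and matrix list beyond these 2, and the few genes called only under an alternative, are named because of their values. For a gene that is not well above background on any array of the lower genotype, a bound replaces the fold: the mean of the higher genotype against the mean, per array, of the higher of the probe's own value and the lowest signal that is well above background.

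The alternatives were quantile or median scaling, normexp background correction with an offset of 50, no filter or a filter on all 6 arrays, the mean of a gene's probes, the authors' table, the slide as a fixed or random block, the slide that holds both genotypes alone, a block for the replicate number, array weights, an intensity trend with a robust variance, each array left out in turn, other thresholds, a plain two-group test, and other set tests and distances. The first file block of each array gives its slide, and slides and scans coincide 1 to 1. Only slide 2 holds both genotypes. With the slide as a fixed block, the genotype difference therefore comes only from WT replicate 3 against Prss54KO replicates 1 and 2. Chosen after the data were seen were the comparison of each mouse with the others of its genotype along chromosomes (windows of 10 Mb on each side of a centre every 5 Mb with at least 50 genes, 490 windows, deviations divided by the mean of genes in the same of 20 signal bins, 1000 shuffles of genes), the windows of differences between genotypes, the counts at an unadjusted p under 0.05, slide 2 as a covariate, the placement of Cngb1 by another probe, and the genes near Prss54 without the 3, or within 1 Mb without the 1, that differ most. Whether an alternative moved the Prss54 result was first judged by its unadjusted p, under which all 20 alternatives stayed the same, and after those values were seen by its adjusted p, the threshold fixed for genes.

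The pipeline was tested on simulated values for the comparison of Prss54KO with WT, drawn for the 19398 genes with the spread of the real arrays and 50 genes changed at each fold. It recovered 66% of genes changed 1.5-fold, 94% of those changed 2-fold, 96% at 3-fold and 100% at 5-fold, and it called 12 unchanged genes. A simulated shift of 1 list was recovered with an adjusted p of 1.05e-08 and 0 other lists were called; the genes near Prss54 gave a permutation p of 0.647 without and 5e-04 with simulated shifts of 0.3. Real arrays share structure between genes that these simulations leave out. With 50 changed genes at each fold, the adjusted threshold is also easier to pass than where few genes change. On the real arrays Prss54, 2.96-fold lower, had limma's adjusted p of 0.0766 and did not pass. The recoveries therefore do not show that changes of these sizes are absent. The number of arrays limits the precision: the median SE of a log2 difference was 0.08.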

Results

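Testis RNA from 3 WT mice and 3 mice lacking Prss54 was hybridised to 1-colour mouse expression arrays, to find which transcripts of the testis differ when this gene is disrupted. Prss54 belongs to the serine protease family. The median processed signal of an array lay between 203.1 and 219.7 intensity units, and the levels of all genes correlated between arrays at r of 0.994 to 0.997. The arrays stood on 3 slides, each scanned separately: WT replicates 1 and 2 on slide 3, WT replicate 3 with Prss54KO replicates 1 and 2 on slide 2, and Prss54KO replicate 3 on slide 1.

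Prss54 itself was the gene with the smallest p of all 19398 tested. Its only probe gave a processed signal of 24316 ± 1727 (SD, n = 3) in WT and 8421 ± 1042 (SD, n = 3) in Prss54KO. On the normalized scale the Prss54KO level was 2.96-fold lower (95% interval 2.48 to 3.52), a log2 difference of -1.56 with an SE of 0.10. All 3 Prss54KO mice lay below all 3 WT mice, the exact permutation p was 0.1, the smallest that 3 against 3 can give, and limma's adjusted p was 0.0766, short of the 0.05 threshold. The remaining signal, 33.8% of the WT level, was well above background on all 3 Prss54KO arrays. The probe, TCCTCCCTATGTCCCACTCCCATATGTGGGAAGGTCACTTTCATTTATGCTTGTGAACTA, lies at positions 98082993 to 98083052 of chromosome 8 (mm9). Which part of the gene was deleted is not given in the sources used here; if the probe lies outside that part, its signal does not check the labels. On slide 2 alone the log2 difference was -1.61, with limma's adjusted p at 0.866 for 1 WT against 2 Prss54KO arrays.

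**Figure D1:**
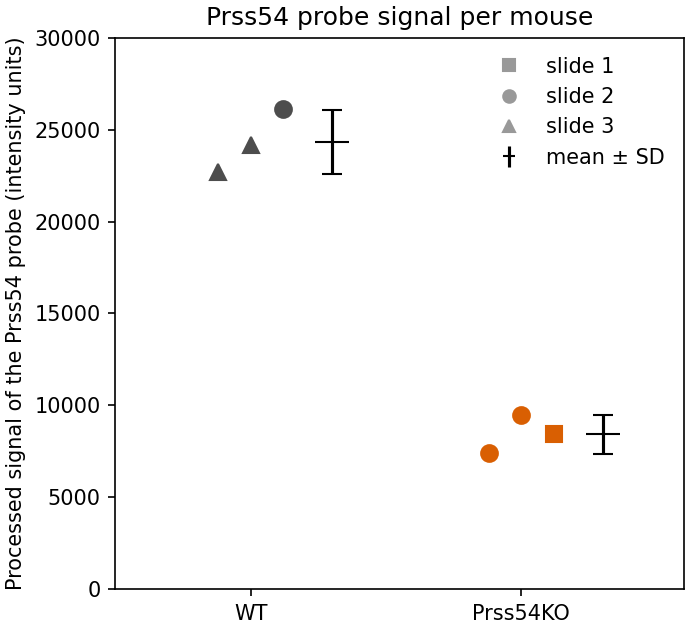
Processed signal of the Prss54 probe (vertical axis, linear intensity units, from 0) for each WT and Prss54KO mouse, with the slide as the symbol and the mean ± SD of 3 mice beside the points. The WT mice lie between 22677 and 26120 and the Prss54KO mice between 7381 and 9466.

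Beyond Prss54, the testis transcriptomes of the genotypes were close to each other. Of the 19398 genes, 89.4% differed by less than 0.2 on the log2 scale, and 51 by more than 1. With limma, 0 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 642 genes, 338 higher and 304 lower in Prss54KO, where chance alone gives 969.9. That count ran from 384 without WT replicate 1 to 1259 without WT replicate 3, and with array weights it was 1177, so it did not stay below the chance count. In 7.79% of genes the genotypes did not overlap, against the 10% that chance gives for 3 against 3.

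The gene next in order was Cngb1, a subunit of the cyclic nucleotide-gated channel of rod photoreceptors, which was 1.75-fold higher in Prss54KO (log2 difference 0.81, SE 0.06) with limma's adjusted p at 0.0766. It passed the threshold in 2 alternatives, the filter on all 6 arrays and the robust variance with an intensity trend. A dimmer probe of Cngb1 gave 0.92 (SE 0.10) as well. The files place the brighter probe on chromosome 5 and the dimmer one on chromosome 8 at 97763334 to 97763393 (mm9), and the RefSeq table orders Cngb1 8 protein-coding genes away from Prss54. The splicing-related gene Gpkow was 0.74 higher (SE 0.08, limma's adjusted p 0.373), but its other probe differed by 0.07 (SE 0.09). The remaining genes taken by smallest p did not pass either (limma's adjusted p of 1 after rounding, 0.99994). Higher were the interferon-induced GTPase gene Gbp9 by 0.43, the oocyte-type NLR gene Nlrp4e by 0.62 and the cytokine gene Il1b by 0.33. Il1b was dim, at a level of -5.21 in WT and -4.87 in Prss54KO, and its difference ran from 0.12 to 0.38 in the alternatives. Lower were Naip2, an inflammasome sensor, at -0.46 and above background on 1 of 3 Prss54KO arrays, the matrix protein gene Ccdc80 at -0.35, and the G protein subunit gene Gng2 at -0.42. Iqcj was not well above background on any Prss54KO array and was at least 1.18-fold lower there.

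With the settings fixed beforehand, no list of germ cells or their products passed. The acrosome list, genes of the secretory vesicle that caps the sperm head, had 37 of 43 members above 0 and a median difference of 0.04, with a camera adjusted p of 0.118 and an adjusted p of 0.953 with an estimated correlation. It passed as higher in 4 of 20 alternatives, with array weights (median 0.07, camera adjusted p 0.00220) and without WT replicate 3, Prss54KO replicate 1 or Prss54KO replicate 3, while its median was -0.01 without Prss54KO replicate 2 and 0.00 on slide 2 alone. Its members with the smallest p were Dcst2 at 0.23 (SE 0.12) and Acrbp, which encodes the proacrosin-binding protein, at 0.09 (SE 0.05). Genes of acrosome formation had a median of 0.00 over 58 members; Rab3a, a vesicle GTPase, stood at -0.16 and Usp8 at 0.12. Sperm-egg binding and fusion genes had a median of 0.03 over 34 members, with Tmem81 at 0.13, and the ADAM proteases of the testis had a median of 0.03 over 17, with Adam6b at -0.14 and Adam1b at 0.09. The serine proteases of the testis, the family of Prss54, had a median of -0.04 over 23 members; Pcsk4 stood at 0.14 and Prss21, a testis serine protease, at 0.10. Sperm flagellum genes had a median of 0.02 over 68 members, with the dynein heavy chain gene Dnahc1 at 0.13 and Tekt4 at 0.10. Sperm chromatin genes had a median of -0.01 over 26, with Ipo4 at 0.09 and Brdt at 0.06. Along the germ line, medians were 0.00 for 28 spermatogonial genes (Ccnd2 at -0.24 and Rarg at 0.18) and 0.00 for 50 meiotic genes (Plk1 at 0.16 and Ccna1 at 0.13). The median was 0.01 for 38 round spermatid genes (Cst13 at -0.26 and Pgam2 at 0.08). Cst13 was lowest in Prss54KO replicate 3 and ran from -0.37 to -0.07 with 1 array left out. Without Prss54KO replicate 3 the sperm-egg, flagellum and round spermatid lists passed as higher, with medians of 0.05, 0.05 and 0.06, and the round spermatid median was -0.04 without Prss54KO replicate 2. Lists share genes, so these calls are not independent. Of the genes on the array, 19 of 36 sperm-egg, 17 of 43 acrosome and 13 of 38 round spermatid genes are also in other lists. For the flagellum list it is 6 of 68. No member of the lists in this paragraph passed the threshold over all genes or adjusted over the list alone, with limma.

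All 24 measured genes of the fibroblast and extracellular matrix list were lower in Prss54KO, with a median difference of -0.17 and a camera adjusted p of 1.51e-09. The call was lost with an estimated correlation (p = 0.0575, adjusted p = 0.770) and with fry (adjusted p = 0.952). The fibrillar collagen genes differed most among its 9 collagens, Col1a1 by -0.73 (SE 0.29) and Col3a1 by -0.67 (SE 0.25). A much dimmer Col3a1 probe gave 0.06. Prss54KO replicate 2 had the lowest level of both genes, and with 1 array left out Col3a1 ran from -0.87 to -0.39. The small proteoglycan gene Lum stood at -0.94 (SE 0.44) and the elastic fibre gene Fbln5 at -0.24 (SE 0.07). The matrix gene Sparc at -0.01 and Pdgfra, a receptor of interstitial cells, at -0.03 hardly differed. None of the 24 passed over all genes or adjusted over the list alone. Relative to the WT mean, the list's median was -0.15, -0.24 and -0.06 in Prss54KO replicates 1, 2 and 3 and -0.01, -0.10 and 0.04 in the WT replicates, so Prss54KO replicate 3 lay inside the WT range. Without Prss54KO replicate 2 the median difference was -0.11, and on slide 2 alone, as with the slide as a block, it was -0.21.

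With the same settings, the other somatic lists did not pass, although some did in alternatives. Endothelial genes had a median of -0.07 over 21 members (camera adjusted p 0.115), with Cdh5, the endothelial cadherin, at -0.18 and Plvap at -0.16; both lie on chromosome 8, Cdh5 within 10 Mb of Prss54. Peritubular and smooth muscle genes had a median of -0.04 over 18, with Itga8 at -0.25 and Ptch1 at 0.15. Leydig cell and steroid genes had a median of -0.03 over 42, with Star, the cholesterol carrier that starts steroid synthesis, at -0.58 (SE 0.24) and Hsd17b11 at 0.12. With 1 array left out, Star ran from -0.84 to -0.37. Sertoli cell genes had a median of 0.01 over 42. The stem cell niche factor Gdnf, well above background on 2 of 3 Prss54KO arrays, stood at 0.20 and Defb19 at 0.20. Macrophage and immune genes had a median of -0.05 over 34, but Prss54KO mice lay on both sides of the WT mean (0.13, -0.26 and -0.03 in replicates 1, 2 and 3), and the median was 0.06 without Prss54KO replicate 2 and -0.12, passing as lower, without Prss54KO replicate 1 (camera adjusted p 0.0294). Genes of this list with the smallest p were Il1b at 0.33 and S100a9, above background on 2 WT and 1 Prss54KO arrays, at -1.77 (SE 0.97). With the slide as a block, the peritubular list (median -0.07) and the adipose list (median -0.34) passed as lower. Their camera adjusted p at the preset correlation were 0.0327 and 0.0309. Without the block and with an estimated correlation, camera gave adjusted p of 0.953 and 0.770 for them. The difference with the block rests on slide 2, whose only WT array is WT replicate 3. Relative to the WT mean, the adipose median was 0.17 in that mouse and -0.04 and -0.13 in WT replicates 1 and 2. All 3 Prss54KO mice lay inside this WT range. The peritubular median was -0.06 and -0.08 in Prss54KO replicates 1 and 2, but 0.05 in Prss54KO replicate 3, above every WT mouse. Without a filter on dim probes the endothelial list passed as lower. With 1 array left out, the endothelial list passed as lower without WT replicate 1 or Prss54KO replicate 3, the peritubular list without Prss54KO replicate 3 and the Leydig list without WT replicate 2.

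Lists for cells carried along by dissection and for stress pathways did not pass with these settings either; in alternatives the adipose list passed as lower in 3 and the interferon list in 1, without Prss54KO replicate 1 (camera adjusted p 0.000428). Medians were -0.03 for 9 red blood cell genes (Tfrc at -0.11 and Hba-a2 at -0.61) and 0.05 for 15 epididymal genes (Defb41 at 0.21 and Lcn9 at 0.52). The median was -0.05 for 13 adipose genes (Retn at -0.35 and Plin4 at -0.16). Retn was well above background on 2 of 3 Prss54KO arrays. With 1 array left out, Hba-a2 ran from -0.96 to -0.24, Lcn9 from 0.25 to 0.77 and Retn from -0.53 to -0.10. Medians were -0.02 for 32 immediate early and heat shock genes (Fosl1 at 0.21 and Cyr61 at 0.21) and 0.00 for 28 unfolded protein response genes (Xbp1 at -0.13 and Ern1 at 0.10). The median was -0.03 for 34 apoptosis genes (Apaf1 at -0.17 and Trp53inp1 at 0.12). Apaf1 was well above background on 1 of 3 Prss54KO arrays. Autophagy genes had a median of 0.02 over 36 (Atg10 at 0.13, with a dimmer probe at -0.20, and Ctsz at -0.11), cholesterol synthesis genes -0.02 over 23 (Mvk at 0.17 and Sc5d at -0.09), interferon genes -0.01 over 23 (Ifi27l1 at -0.10 and Ddx58 at -0.12) and Y-linked genes 0.02 over 11 (Ddx3y at -0.07 and Ssty1 at 0.13). Median, mean and test differed in sign for 4 lists: spermatogonia, acrosome formation, round spermatids, and immediate early genes.

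**Figure D2:**
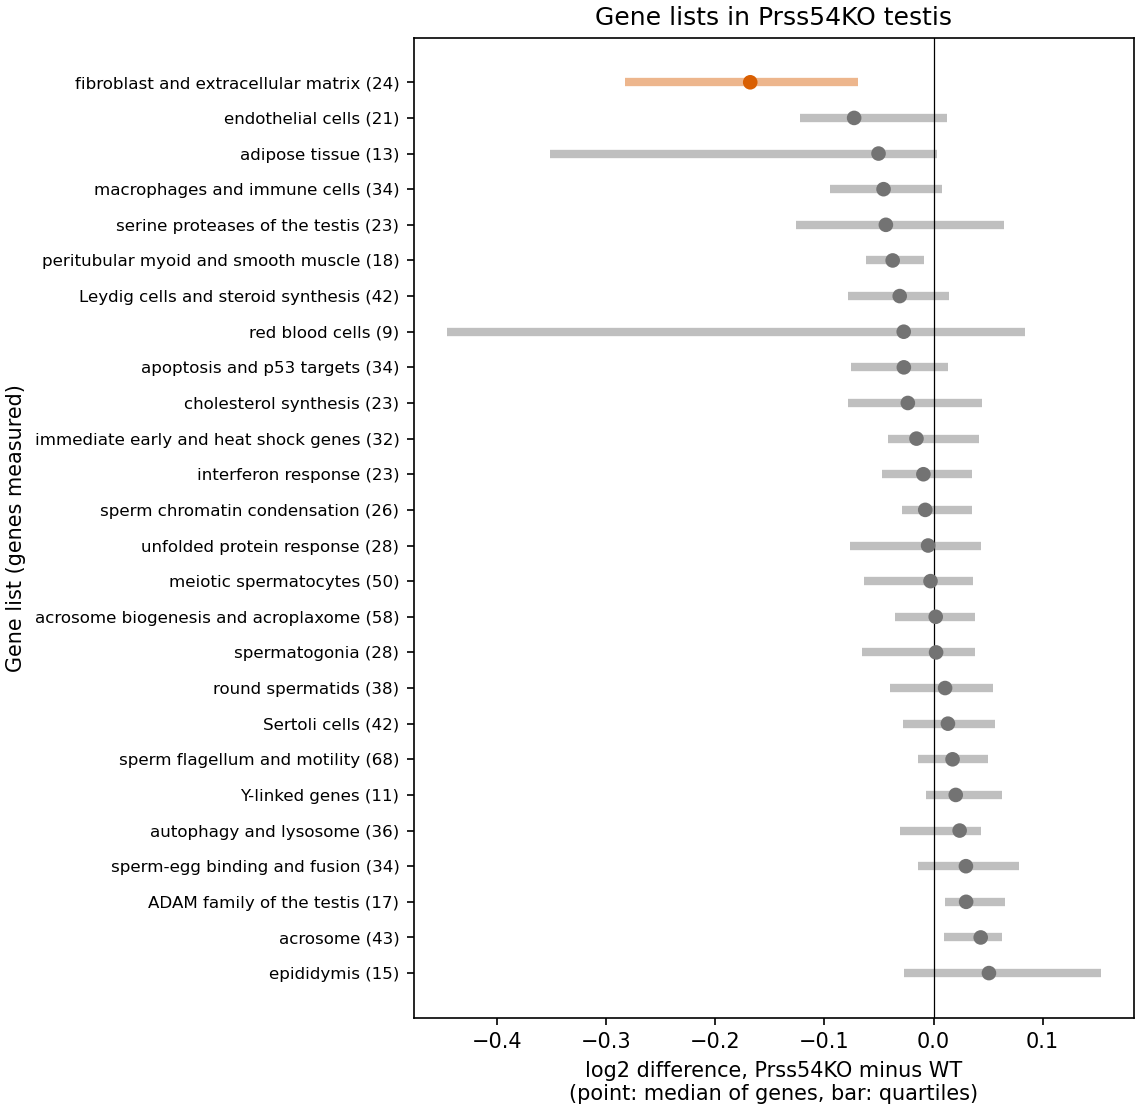
Log2 difference, Prss54KO minus WT (horizontal axis), for the 26 gene lists, with the number of measured genes in brackets; points are medians and bars the quartiles of the genes. The fibroblast and extracellular matrix list, the coloured one, has a median of -0.17, and the other lists lie between -0.07 and 0.05.

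The mice are of mixed 129Sv and C57BL/6 background, so genes linked to the disrupted locus were set against the rest of the genome. Around Prss54, genes differed more between genotypes than elsewhere. The 33 tested genes within 1 Mb had a mean absolute log2 difference of 0.187 against 0.0931 for other genes (permutation p 0.00206), and the 141 genes within 10 Mb had 0.151 against 0.0928 (permutation p 2e-05). Sets matched on signal averaged 0.0979. A few genes carry much of this: the excess within 1 Mb, 0.0936, was 0.0491 without 1700121C10Rik (permutation p 0.0354), and that within 10 Mb, 0.0578, was 0.0353 without the 3 genes that differ most (permutation p 0.00377). Within 1 Mb, 8 genes (24.2%) had an unadjusted p under 0.05, 4 higher and 4 lower, against 3.27% of other genes (Fisher's exact p 9.09e-06), but 0 genes passed the adjusted threshold. The permutation and Fisher's exact tests take genes as the units, so their p-values do not measure the spread between mice. The unnamed transcript 1700121C10Rik was 3.05-fold lower (log2 -1.61, SE 0.23). Lower also were the kinesin gene Kifc3 at -0.25 (SE 0.05; another probe -0.10), the chemokine gene Cx3cl1 at -0.29 and Cnot1, a scaffold of the deadenylation complex, at -0.18 (other probes -0.20 and -0.03). Higher were Ciapin1, a gene of iron-sulfur protein assembly, at 0.41 (SE 0.10), Tepp at 0.42, the chemokine gene Ccl17 at 0.64 and Zfp319 at 0.22. With 1 array left out, Ciapin1 ran from 0.30 to 0.48 and Tepp from 0.30 to 0.59. Ccl17 ran from 0.37 to 0.80 and Zfp319 from 0.17 to 0.29. Of the genes next to Prss54, Ccdc113 differed by 0.02 and Gins3 by -0.11. Cngb1, 0.81 higher, is counted with the genes elsewhere throughout this paragraph, because the files place its brighter probe on chromosome 5. They place its dimmer probe within 1 Mb of Prss54. The 3 probes of the kinase gene Csnk2a2 did not give the same value: the brightest differed by 0.02 (SE 0.06) and the dimmer ones by 0.41 (SE 0.07) and 0.72 (SE 0.08), all well above background on 6 arrays, and with the mean of its probes the gene differed by 0.38 (limma's adjusted p 1 after rounding). Among 490 windows along the genome, those centred at 105, 100 and 110 Mb of chromosome 8 had the 3 highest shares of genes at an unadjusted p under 0.05, 11.3%, 10.3% and 10.1%. The window at 115 Mb of chromosome 8 had 9.17%, rank 5. Those at 110 and 115 Mb do not hold Prss54, and those at 90 and 95 Mb, which do, had 5.76% and 5.45%, ranks 43 and 61. By mean absolute log2 difference the windows at 105, 100 and 110 Mb ranked 16, 8 and 40, those at 95, 90, 85 and 80 Mb of chromosome 8 ranked 3, 4, 5 and 6, and the highest was centred at 80 Mb of chromosome 2, at 0.167.

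WT replicate 3 weighed on the values of this region. Its genes in the window centred at 85 Mb of chromosome 8 deviated from the other 2 WT mice 2.66 times as much as genes of equal signal. That window ends short of Prss54. At 95 Mb the value was 2.59 and at 100 Mb, the window nearest to Prss54 in its centre, 1.29 (permutation p 0.986). At 105, 110 and 115 Mb it was 1.01, 0.93 and 0.95, so WT replicate 3 did not stand apart in those windows. Without WT replicate 3, the excess within 10 Mb was 0.0260 (permutation p 0.0501) and that within 1 Mb 0.0650 (permutation p 0.0273). Without that mouse, 12.8% of genes within 10 Mb had an unadjusted p under 0.05 against 6.44% elsewhere (Fisher's exact p 0.00531). With all arrays these shares were 9.22% and 3.26%. Within 1 Mb the shares were 24.2% against 6.46% without that mouse (Fisher's exact p 0.000987) and 24.2% against 3.27% with all arrays. On slide 2 alone, where WT replicate 3 is the only WT array, the excess within 10 Mb was 0.126. Without Prss54KO replicate 1 it was the counts that did not pass, 6.38% against 4.66% within 10 Mb (Fisher's exact p 0.314) and 12.1% against 4.66% within 1 Mb (Fisher's exact p 0.0662), while the excess was 0.0459 (permutation p 0.00127) and 0.0618 (permutation p 0.0243).

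**Figure D3:**
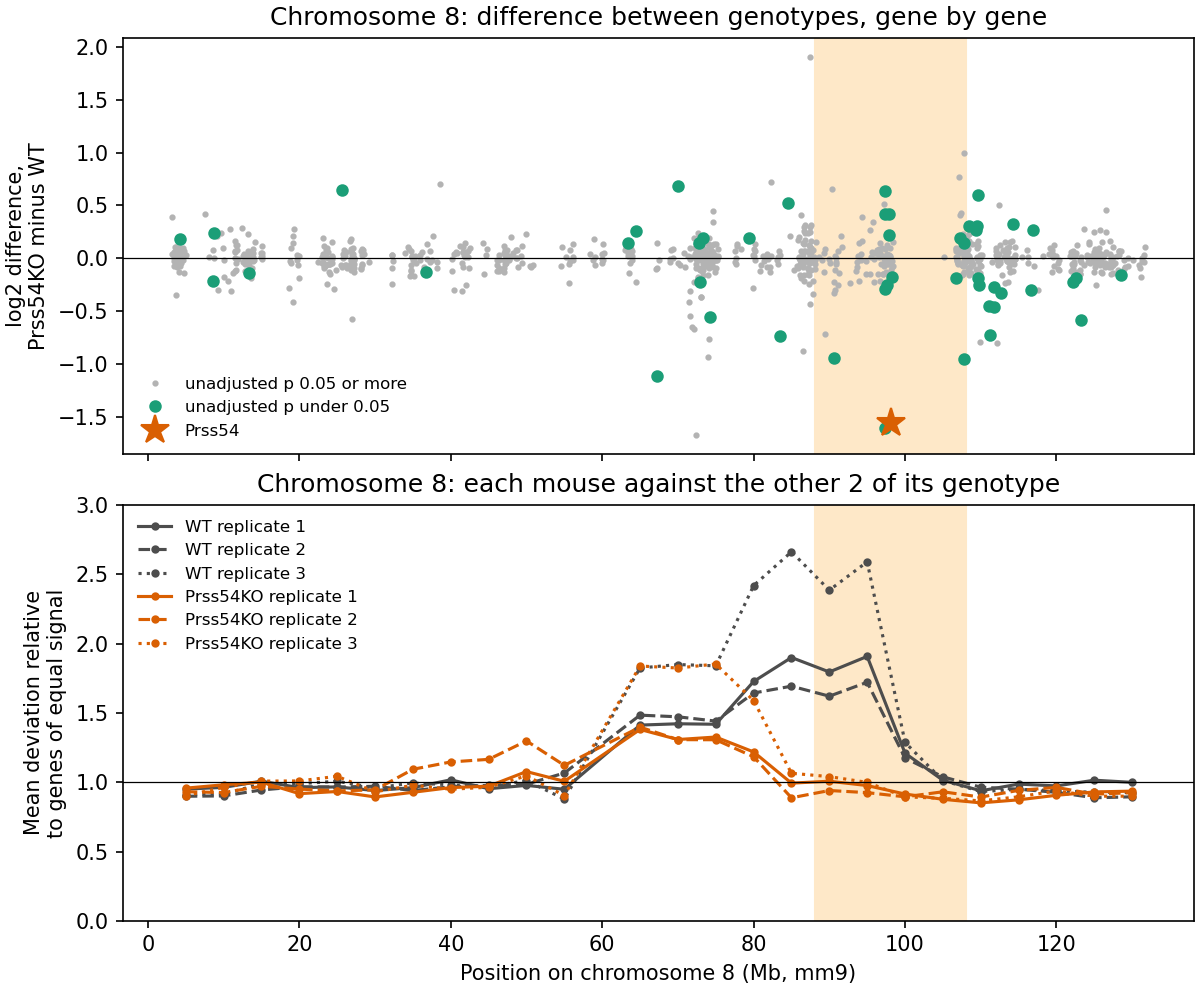
Upper part: log2 difference, Prss54KO minus WT, of each tested gene against its position on chromosome 8 (Mb, mm9), with genes at an unadjusted p under 0.05 coloured and Prss54 as a star; the shading spans 10 Mb on each side of it. Lower part: for windows along chromosome 8, the mean deviation of each mouse from the other 2 of its genotype, relative to genes of equal signal (1 is the genome's level); WT replicate 3 reaches 2.66 at 85 Mb and Prss54KO replicate 3 reaches 1.85 at 75 Mb.

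The arrays of slide 2 stood apart from the others more than the genotypes did. The first principal component, 29.6% of the variance, placed the 3 arrays of slide 2 at 3.78 or more and the other 3 arrays at -10.9 or less, while WT and Prss54KO arrays lay on both sides. With the slide as a fixed block, the genotype difference rests on slide 2, that is on WT replicate 3 against Prss54KO replicates 1 and 2. In that fit Prss54 differed by -1.61.

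**Figure D4:**
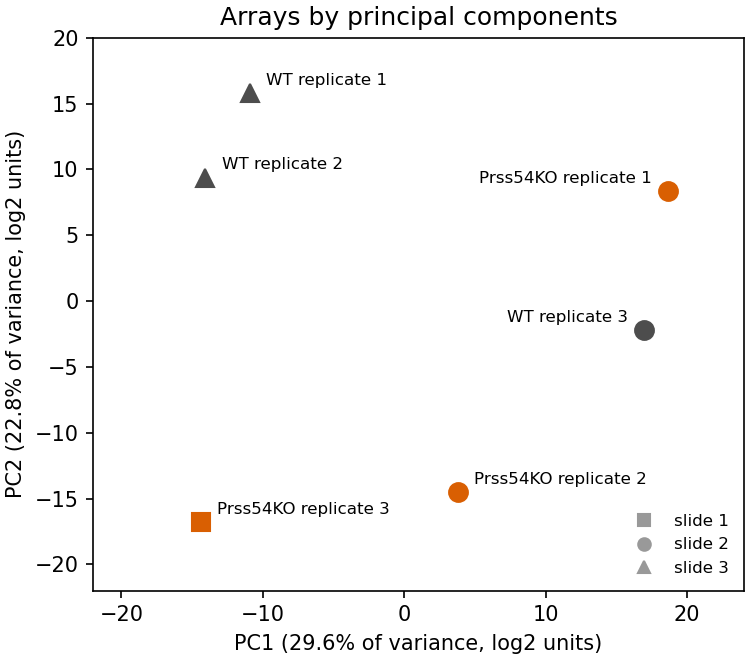
Arrays by their first and second principal components (log2 units; 29.6% and 22.8% of the variance), with the genotype as the colour (WT grey, Prss54KO orange) and the slide as the symbol. The 3 arrays of slide 2 lie at 3.78 or more on the first component, the other 3 at -10.9 or less.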

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

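Slide 2 as a covariate, the genes near Prss54 without the 3, or within 1 Mb without the 1, that differ most, Cngb1 placed by its chromosome 8 probe, and counts at an unadjusted p were chosen after seeing the data. The Prss54 difference stayed between -1.66 and -1.47 in all 20 alternatives, with limma's adjusted p from 0.00491 to 0.866; it passed 0.05 with normexp (-1.54), with the filter on all 6 arrays (-1.56, fewer genes tested) and with the robust variance and trend (-1.56). The count of genes at an adjusted p under 0.05, 0 as reported, was 1 with normexp (Prss54), 2 with the filter on all 6 arrays and 2 with the robust variance (Prss54 and Cngb1 in both), 1 with the slide as a fixed block (Klf1), and 6 at an unadjusted p under 0.05 with at least 2-fold by a plain two-group statistic, which gave 0 after adjustment; those 6 were Prss54, 1700121C10Rik, Samd5, E230025N22Rik, Gpr115 and TC1749263, of which Samd5, Gpr115 and TC1749263 were above background on 0 Prss54KO arrays. The other 20 alternatives gave 0, among them leaving out any array. At an unadjusted p under 0.05 there were 642 genes, 1136 without a filter, 1177 with array weights, and from 384 (without WT replicate 1) to 1259 (without WT replicate 3) with 1 array left out. Lists past the threshold numbered 1 as reported, 2 without a filter, 3 with the slide as a fixed block, 3 on slide 2 alone, 2 with array weights, 0 with fry, 0 with an estimated correlation, and 1 to 7 with 1 array left out. Lists that passed only in alternatives were, as higher, acrosome (4), sperm-egg fusion (1), flagellum (1) and round spermatids (1), and, as lower, peritubular (3), endothelial (3), adipose (3), Leydig (1), macrophage (1) and interferon (1) genes. The slide as a fixed block and slide 2 alone give the same genotype difference, and both are counted for the peritubular and adipose lists. The highest count of lists came without Prss54KO replicate 3, when the round spermatid list passed as higher against a test direction of lower with all arrays. The median of that list lay between -0.0410 (without Prss54KO replicate 2) and 0.0628 (without Prss54KO replicate 3) with 1 array left out. The matrix list, median -0.17 (-0.168), was lost with fry and with an estimated correlation and passed in the other 21 alternatives, from -0.215 to -0.110. Alternatives that change the scaling, filter, block or arrays keep the preset correlation of 0.01, so they do not test it. The estimated correlation of this list was 0.286. The excess near Prss54 lay between 0.0260 (without WT replicate 3, permutation p 0.0501) and 0.126 (slide 2 alone), and with 1 array left out between 0.0260 and 0.0815; it was 0.0625 with Cngb1 on chromosome 8 and 0.0353 without the 3 genes that differ most, and within 1 Mb 0.0491 without the 1 that differs most. Across alternatives the sign of the test changed in 58 of 520 list values and in 65 of 1832 values of named genes. Replicate numbers do not pair these mice: same-numbered mice had correlations of deviations of -0.04, 0.02 and -0.16. With the replicate block 0 genes and 1 list passed, 780 genes had an unadjusted p under 0.05, Prss54 differed by -1.56 and the excess near Prss54 was 0.0578. The cause of these moves was not tested. Signals near background limit genes such as Iqcj to a bound.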

Other observations

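Tests chosen only after the results were seen are those of single mice along chromosomes, of slide batches for the matrix list and for gene counts, of other stromal cells, of higher genes near Prss54, and of the splits for genes near Prss54 and for gene counts. The comparison of collagens with other members, and the condition that mice of the genotypes lie apart, were added after the first results of the matrix list were seen.

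Single mice stood apart over long stretches of chromosomes. WT replicate 3 deviated from the other WT mice by 2.42, 2.66, 2.39 and 2.59 times the genome's level in the windows centred at 80, 85, 90 and 95 Mb of chromosome 8, its 4 highest of 490, each with a permutation p of 0.001 for the highest window, the smallest that 1000 shuffles give. At 100 Mb its value was 1.29 and at 105 Mb 1.01. Prss54KO replicate 3 deviated by 1.84, 1.82 and 1.85 times at 65, 70 and 75 Mb of chromosome 8 (permutation p of 0.00999, 0.0110 and 0.00799) and by 1.06 at 85 Mb. Prss54KO replicate 2 deviated most on chromosome 2, by 1.88 times at 115 Mb and 1.83 times at 120 Mb (permutation p 0.003 for each). WT replicate 1 deviated by 1.91 times at 10 Mb of chromosome 14 and by 1.91 and 1.90 times at 95 and 85 Mb of chromosome 8 (permutation p 0.001 for each, the smallest possible), and WT replicate 2 deviated most on chromosome 8, by 1.72 times at 95 Mb and 1.69 times at 85 Mb (permutation p 0.003 and 0.00599). Prss54KO replicate 1 had 0 windows with such a p under 0.05. Each mouse is set against only 2 others, so a mouse that differs raises the values of the others too; the values of WT replicates 1 and 2 on chromosome 8 were lower than that of WT replicate 3, and whether they come from it alone was not tested.

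Genes near Prss54 differed more between genotypes than other genes, and a candidate explanation is that alleles of 129Sv origin linked to the disrupted gene differ in expression from those of WT mice. Slides cannot be told apart from mice here: the excess within 10 Mb was 0.126 on the slide that holds both genotypes, but its only WT array is WT replicate 3, so the bound set for that value beforehand decides nothing. Sets matched on signal reached the observed mean with p of 0.000200 only, which argues against dim probes; 129Sv sequence under probes made for another strain would lower signals, but 6 of 141 genes were higher at an unadjusted p under 0.05, more than elsewhere (exact binomial p 0.0362), if the WT mice carry the sequence the probes match; for lower genes, 1 of 3 further probes was lower too (Cnot1 at -0.20, against Cnot1 at -0.03 and Kifc3 at -0.10), and poor binding cannot be told apart from lower expression with so few probes. Linked alleles would give smaller differences over 40 Mb away on chromosome 8, where the mean was lower by 0.0648 (permutation p 2e-05). That far mean, 0.0859, lay near the 0.0928 of all genes elsewhere, so any cause local to this region gives the same. The value therefore does not single out linked alleles. A WT mouse of another haplotype could account for part of the excess. Without WT replicate 3 the excess was 0.0260 in place of 0.0578 within 10 Mb. Within 1 Mb it was 0.0650 in place of 0.0936, so a part remained there (permutation p 0.0273). In the splits of the 6 arrays, 1 of 10 gave as large an excess, the real one at 0.0578 with the highest other at 0.0494, and 10 splits are too few for a share under 0.05; no genotypes at strain markers were analysed here, and an effect of losing Prss54 on these genes stays open.

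Matrix genes were lower in Prss54KO as a list by camera at the preset correlation, but not with an estimated correlation (adjusted p 0.770) or with fry (adjusted p 0.952). A slide effect cannot be told apart from a difference between mice: the median was -0.213 on the slide that holds both genotypes, which has 1 WT array. Less of all stromal cells could not be settled: the list's median lay below that of 115 genes of 4 other stromal lists by 0.128 (-0.128, permutation p over genes 1e-05, the smallest possible), yet per mouse that gap was -0.0340 in Prss54KO replicate 3 and -0.0638 in WT replicate 2. Fewer fibroblasts could not be settled either. The 15 members other than collagens were all below 0, with a median of -0.110 (sign-flip permutation p 0.00725). They belong to the list whose 24 genes were all lower, so this outcome was already fixed and decides nothing. The collagens lay lower still by -0.178 (permutation p 0.0129). Genes of a list move together between mice, which these permutations ignore. In the splits of the 6 arrays, 2 of 10 gave as small a camera p, the real one at 5.82e-11 and the smallest other at 5.26e-11, and 10 splits cannot give a share under 0.05; a change of the knockout's connective tissue stays untested.

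The arrays hold a structure that is stronger than genotype. The split of slide 2 against the other slides gave 2341 genes at an unadjusted p under 0.05 and 7 at an adjusted p under 0.05. Genotype gave 642 and 0, and the next split gave 1751 at an unadjusted p under 0.05. A slide or scan batch could give this. With 1 scan per slide and a single mouse on slide 1, it may also be mice that differ. That all 10 splits gave as many genes at an adjusted p under 0.05 (7 as the highest other) is fixed by genotype's count of 0 and says nothing. All 10 splits called as many gene lists, where genotype gave 1 and the highest other was 9. With the slide as a fixed block, the genotype difference rests on slide 2, which has 1 WT array, so that fit does not separate slides from mice.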
